A study of Mus musculus with 11 samples.

How the data were processed

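The series holds RNA-seq of mouse embryonic faces of 2 genotypes and ChIP-seq of wild-type face, all at embryonic day 11.5. Per the labels, the tissue was facial mesenchyme, taken between the arch (spelled bronchial there) and the edge of the forebrain, and the strain background was C57BL6/j. Each RNA tube received 72000 Drosophila S2 cells as a spike, and the RNA libraries were made with the TruSeq kit and shared a HiSeq2000 flow cell, per the labels' protocols.

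The RNA values are raw read counts per Ensembl gene, as deposited. HTSeq, DESeq and the build mm9 are named in the submitters' processing notes. The aligner, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes are uncertain. The table has 38561 gene rows, of which 36639 were matched to a symbol. The fly spike-in was not analysed here. Each ChIP library has 1 deposited file of coverage in bins of 50 bp. The coverage signal was scaled by the authors so that its mean over all bins is 1, as seen from the values. The peak score in the deposited peak lists is the authors' own, and its scale is not given in the sources used here. Bowtie2, MACS, bedtools and mm9 are named in the submitters' processing notes. Peaks were called on 1 library per mark. Differences between neighbouring bins had their most negative autocorrelation at 250 bp for H3K27ac, 750 bp for H3K4me1 and 1750 bp for input, as smoothing or read extension over different lengths could give. Which was done is not stated in the sources used here, so fine detail was not compared between the 3 tracks.

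The 8 RNA libraries were compared as 4 del(8-17) homozygous against 4 wild type with edgeR 4.0.16 (R 4.3.3). Genes were kept with filterByExpr, which left 13720, libraries were scaled by TMM, and the quasi-likelihood F test was used with legacy=FALSE. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error of a log2 fold change was derived from the F statistic. The log2 CPM of Myc was also compared by an exact permutation test. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, and again with a correlation estimated per list. Of 29 lists fixed before the data were examined, 26 had at least 5 tested members and were tested; the sex-linked list, the replication-dependent histones and the skeletal muscle and heart list were not. Symbols were brought up to date with the synonyms of GRCm38.p6, which was also used to assign genes to chromosomes but for no position in the text, and 804 of 812 list entries had a row in the table.

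Genes named in the text were chosen by a rule set before the data were examined. It takes the tested neighbours of Myc, and the 10 largest rises and 10 largest falls among called genes with mean log2 CPM above 0 and no overlap between groups. It also takes up to 4 members of each called list and up to 2 of every other list, 7 further genes (Mycn, Cdkn1a, Ncl, Npm1, Odc1, Cdk4 and Ccnd2), and Xist with the Y-linked genes. Genes outside the rule are marked where they appear.

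Library totals ranged from 3939159 to 23094852 counts, a 5.86-fold range, so genes of low count were measured least precisely in mutant replicate 3. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom between pairs was 2.03 or more. The labels give 2 mothers, and each litter held as many mutants as wild types. Deviations from the group means correlated at -0.0577 for the 1 pair of litter 214262 and at -0.00741 on average within litter 214676, against 0.0200 between litters.

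The tests were checked on simulated counts with the means and library sizes of the mutant against wild type comparison. Changed genes were drawn from those with mean CPM above 1. Genes were simulated independently in a single run, each with the average spread at its mean expression. Over 13612 tested genes, 58.0% of genes changed by 0.3 on the log2 scale were recovered, 80.0% of those changed by 0.5, 96.0% of those changed by 1 and all of those changed by 2. Unchanged genes made up 7.5% of the calls.

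The alternatives were DESeq2 size factors, no filter on low counts, the litter as a block, litter 214676 alone, DESeq2 1.42.0, limma voom, 2 other edgeR settings, thresholds of 0.1 and 0.01, fry, and each library left out in turn. Alternatives chosen after seeing the data were the removal of the 2 libraries with Y-linked transcripts, thinning of every library to 3939159 counts, and removal of Myc from every list.

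Peak lists were compared by overlap of at least 1 bp with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Coverage over a peak is the mean over the 50 bp bins it touches, relative to the genome mean. With 1 library per mark, ChIP values have no replicate check. Positions are 1-based in mm9. No gene annotation of mm9 was used here, so no peak is assigned to a gene.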

Results

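RNA was sequenced from 4 wild-type and 4 del(8-17) homozygous littermate faces at embryonic day 11.5, and histone marks were profiled in wild-type face by 1 H3K27ac, 1 H3K4me1 and 1 input library. H3K27ac marks active promoters and enhancers, and H3K4me1 marks enhancers. The series title names a locus linked to cleft lip as a remote enhancer of Myc. Wild-type replicates 1 to 4 held 7429267, 12526628, 12200205 and 7671251 counts. Mutant replicates 1 to 4 held 5658638, 9021130, 3939159 and 23094852 counts.

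Myc, a transcription factor that promotes growth and ribosome production, was the first check of the genotype labels. It fell in del(8-17) homozygous faces to 5.62 ± 0.659 CPM from 33.7 ± 0.522 CPM in wild type (SD, n = 4 each), which is 16.7% of the wild-type mean. The log2 fold change was -2.60 (SE 0.0927, edgeR adjusted p = 6.73e-11), and all 4 mutants lay below all 4 wild types. An exact two-sided permutation test of log2 CPM gave p = 0.0286, the smallest that 70 splits allow. The test sets the litters aside. Only 20 ways to part the libraries balance the litters, and these allow no share under 0.05.

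Of the 15 tested members of the list of Myc neighbours, 1 passed over all genes, which was Myc, and 3 when adjusted over the list alone. The noncoding gene Pvt1, which lies beside Myc, had a log2 fold change of -0.81 (SE 0.202, edgeR adjusted p = 0.0808), with 4.25 ± 0.833 CPM in wild type and 2.34 ± 0.570 in mutants (SD, n = 4). Sla had -0.85 (adjusted p = 0.0866), Asap1 -0.037, St3gal1 0.035 and Trib1 0.041. The list had a median of -0.0020 and a mean of -0.28 (camera adjusted p = 0.0546). This list holds Myc itself, and with Myc taken out, an alternative chosen after seeing the data, adjusted p was 0.535. With Myc in it, adjusted p was 0.256 without a filter on low counts, and 0.00810, 0.0129 and 0.0487 without mutant replicate 4, wild-type replicate 2 or wild-type replicate 4. Over all 8 libraries it was adjusted p = 0.194 with an estimated correlation. The related genes Mycn, at 0.23 (adjusted p = 0.330), and Mycl, at 0.18 (adjusted p = 0.142), did not pass.

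**Figure D1:**
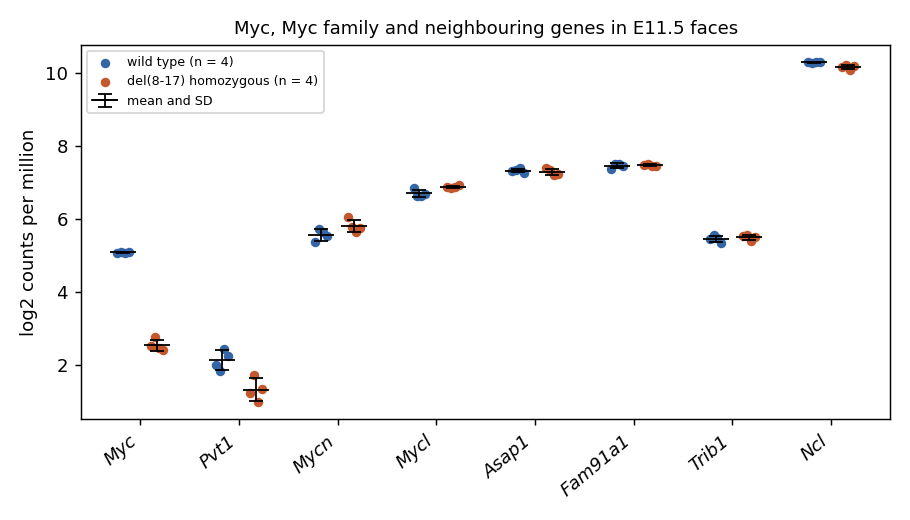
Log2 CPM of 8 genes in each library, with the mean and SD of each group (n = 4); blue points are wild type and orange points del(8-17) homozygous. Myc lies at 5.08 on average in wild type and at 2.53 in mutants, with no overlap.

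Across the 13720 genes tested, 142 changed, of which 36 were higher and 106 lower in mutants. Of these, 38 fell and 4 rose by more than 2-fold, while 88 changed by less than 1.5-fold. The groups did not overlap for 784 genes, or 5.71% of those tested, where chance gives 2.86%. The number of higher genes was the less stable: it was 52 without wild-type replicate 1, and between 14 (without mutant replicate 2 or mutant replicate 4) and 23 without any other library. The total was 86 without mutant replicate 4.

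Apart from Myc, the largest falls among named genes were in genes of macrophages and other blood cells. Of 14 tested members of the list of macrophages and blood cells, 12 fell and 2 did not pass, and 13 fell when adjusted over the list alone. The median log2 fold change was -1.91 (camera adjusted p = 4.43e-36, and adjusted p = 0.0102 with an estimated correlation). Csf1r, the growth factor receptor that macrophages need, fell from 13.7 ± 1.22 to 2.23 ± 0.548 CPM (SD, n = 4; log2 -2.74, SE 0.150, edgeR adjusted p = 2.75e-08). Adgre1, which encodes the macrophage marker F4/80, had -2.97, and the complement genes C1qb and C1qc had -2.50 and -2.30. Outside the list, Ly86 (-2.98), the lysosomal protease gene Ctss (-2.97), Mpo (-2.73), Myo1f (-2.59), Mpeg1 (-2.42) and the immunoglobulin gene Ighm (-3.39) fell. Several of these lay close to 0 in mutants, with 0.239 CPM on average for Ly86, 0.257 for Ighm, 0.493 for Mpo and 0.494 for Myo1f. The size and order of their falls are therefore uncertain. Ighm lay between -3.69 and -2.66 with each library left out.

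Other cell types of the vessels were measured beside them. The erythroid list had a median of -0.076 over 13 members (camera adjusted p = 0.427). None of them passed with edgeR, DESeq2 or voom, and 1 had an unadjusted p under 0.05. Without wild-type replicate 1 the erythroid list was called lower with the preset correlation (camera adjusted p = 2.87e-06), as in litter 214676 alone (5.67e-06). Over all 8 libraries its adjusted p = 0.764 with an estimated correlation. The endothelium list had a median of -0.030 over 17 members (camera adjusted p = 0.0508), of which 0 passed with edgeR, DESeq2 or voom and 1 had an unadjusted p under 0.05. With the litter as a block it was called lower (adjusted p = 0.0446), as in litter 214676 alone (0.0179), without a filter on low counts (0.0352) and without the libraries with Y-linked transcripts (0.0472), but not with an estimated correlation (0.350). It was also called lower without wild-type replicate 1 (adjusted p = 0.0192), wild-type replicate 4 (0.0327), mutant replicate 1 (0.0441) or mutant replicate 3 (0.0163).

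Messenger RNAs of the cytosolic ribosome fell by a small amount. Of 64 tested members, 29 fell, none rose and 35 did not pass, and 46 fell when adjusted over the list alone. The median was -0.23 (camera adjusted p = 1.89e-54, and adjusted p = 0.00807 with an estimated correlation). Rplp0 fell from 711.5 ± 23.2 to 537.3 ± 25.2 CPM (SD, n = 4; log2 -0.40, SE 0.0385, edgeR adjusted p = 2.84e-05). Rplp1 had -0.36, Rps20 -0.32 and Rpl13a -0.29, and all of these passed. These genes have processed pseudogenes, and how shared reads were counted is not given in the sources used here, so the value of each single gene is uncertain.

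Ribosome biogenesis genes shifted down as a list, with a median of -0.098 over 83 members (camera adjusted p = 6.01e-17, and adjusted p = 0.0404 with an estimated correlation). With edgeR 0 of the 83 passed over all genes, 10 did when adjusted over the list alone, 25 had an unadjusted p under 0.05, and DESeq2 and voom called 1 each. The nucleolar gene Ncl had -0.14 (adjusted p = 0.0802) and Nhp2 -0.22 (adjusted p = 0.0866). Among other genes often linked to Myc, Npm1 had -0.13, Odc1 -0.033, Cdk4 -0.023, Ccnd2 0.048 and Cdkn1a 0.12, and none of these passed.

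Targets of Fgf signalling rose as a list. All 14 tested members were above 0, 3 passed over all genes and 11 when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 6.85e-14, and adjusted p = 0.0369 with an estimated correlation). The transcription factor gene Etv5 rose by 0.27 (adjusted p = 0.00730), the phosphatase gene Dusp6 by 0.22 (adjusted p = 0.0436) and Spry4, an inhibitor of the pathway, by 0.27 (adjusted p = 0.0479). Dusp6 and Spry4 each lost the call in 7 of the 8 fits that left out 1 library, and Etv5 in 0. Etv1 had 0.29 (adjusted p = 0.0614).

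Bmp and Tgfb targets and genes of orofacial clefting also shifted up. In the first list 2 of 18 members rose, and 5 when adjusted over the list alone (median 0.14, camera adjusted p = 4.59e-08, and adjusted p = 0.0117 with an estimated correlation). Bmp7 rose from 113.9 ± 6.04 to 136.6 ± 2.43 CPM (SD, n = 4; edgeR adjusted p = 0.00385), and Gata2 by 0.30 (adjusted p = 0.0178). In the clefting list 1 of 43 members rose, and 6 when adjusted over the list alone (median 0.094, camera adjusted p = 7.79e-07, and adjusted p = 0.0182 with an estimated correlation). That gene, the growth factor gene Pdgfc, rose by 0.20 (adjusted p = 0.0162). Bmp4, which is in both lists, had 0.28 (adjusted p = 0.0866), and Wnt9b had 0.27 (adjusted p = 0.0903). Of the tested clefting genes, 15 of 43 were also members of another list. So were 3 of 18 Bmp and Tgfb targets, 3 of 14 Fgf targets and 4 of 21 surface ectoderm genes, so the lists are not independent. Gata2 lost the call in 2 and Pdgfc in 4 of the 8 fits that left out 1 library. Beside these lists and the Fgf targets, markers of surface ectoderm had a median of 0.16, with 19 of 21 above 0 (camera adjusted p = 1.75e-09, but adjusted p = 0.150 with an estimated correlation); Krt15 had 0.45 and Grhl2 0.21, and neither passed.

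**Figure D2:**
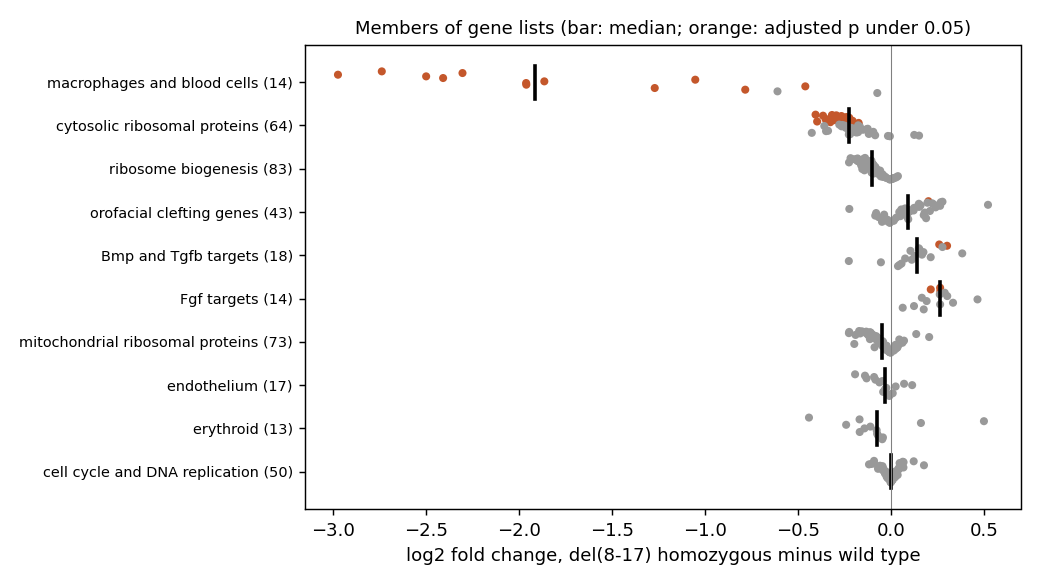
Log2 fold change, mutant minus wild type, of each tested member of 10 gene lists; black bars are medians and orange points are genes with an adjusted p under the threshold of 0.05. The macrophage list has its median at -1.91 and the cell cycle list at -0.00064.

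Camera called 13 of the 26 lists with the preset correlation, and the 6 described so far as shifted hold with an estimated one. The other 7 calls were lost with it. For lists that were lower in mutants, this left adjusted p = 0.120 with an estimated correlation for Myc-responsive metabolism, for translation factors and tRNA synthetases and for mitochondrial ribosomal proteins, and 0.212 for hypoxia and glycolysis. Their medians were -0.076, -0.036, -0.047 and -0.056. In the same order 1 of 42, 3 of 38, 0 of 73 and 2 of 15 members fell, and 4, 6, 0 and 3 when adjusted over the list alone. The elongation factor genes Eef2 (-0.27), Eef1a1 (-0.23) and Eef1b2 (-0.20) fell, as did the glycolytic genes Ldha (-0.30) and Aldoa (-0.29) and the kinase gene Pdk1 (-0.27). Aldoa lost the call in 6 and Ldha in 1 of the 8 fits that left out 1 library.

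For lists that were higher, adjusted p with an estimated correlation was 0.150 for surface ectoderm, 0.0734 for Wnt targets and 0.256 for neurons and olfactory placode. Their medians were 0.16, 0.10 and 0.14, and edgeR, DESeq2 and voom called 0 of their 21, 18 and 19 members. Unadjusted p was under 0.05 for 9, 8 and 6 of them. When adjusted over the list alone, 4 ectoderm genes were higher, and 3 Wnt targets were higher and 1 lower.

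The list of 50 cell cycle and DNA replication genes had a median of -0.00064 (camera adjusted p = 0.685), and that of 27 p53 and apoptosis genes had 0.014 (camera adjusted p = 0.685). In each, edgeR, DESeq2 and voom called 0 members, and 1 had an unadjusted p under 0.05. The list of facial mesenchyme and neural crest had a median of 0.055 over 49 members (camera adjusted p = 0.0704), and was called higher without mutant replicate 4 (adjusted p = 0.00277), wild-type replicate 1 (0.0115), mutant replicate 3 (0.0369) or the libraries with Y-linked transcripts (0.0300). These used the preset correlation, and over all 8 libraries its adjusted p = 0.432 with an estimated correlation. The other lists did not pass, with camera adjusted p of 0.208 for heat shock, 0.369 for eye and pigment, 0.501 for the Myc family, neural epithelium and cell cycle inhibitors, 0.510 for Hedgehog targets and 0.838 for immediate early genes. For neural epithelium the test pointed up while the median (-0.0041) and mean (-0.044) lay below 0. For immediate early genes the test and median (0.011) were up and the mean was -0.0051. Without a filter on low counts the eye and pigment list was called lower (adjusted p = 0.000962). The chaperone gene Hsp90aa1 fell by 0.17 (adjusted p = 0.0492) and lost the call in 7 of the 8 fits that left out 1 library. The histone list and the list of skeletal muscle and heart had 4 tested members each, with medians of -0.086 and -0.15, and edgeR, DESeq2 and voom called 0 of them, also at an unadjusted p under 0.05 with edgeR.

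**Figure D3:**
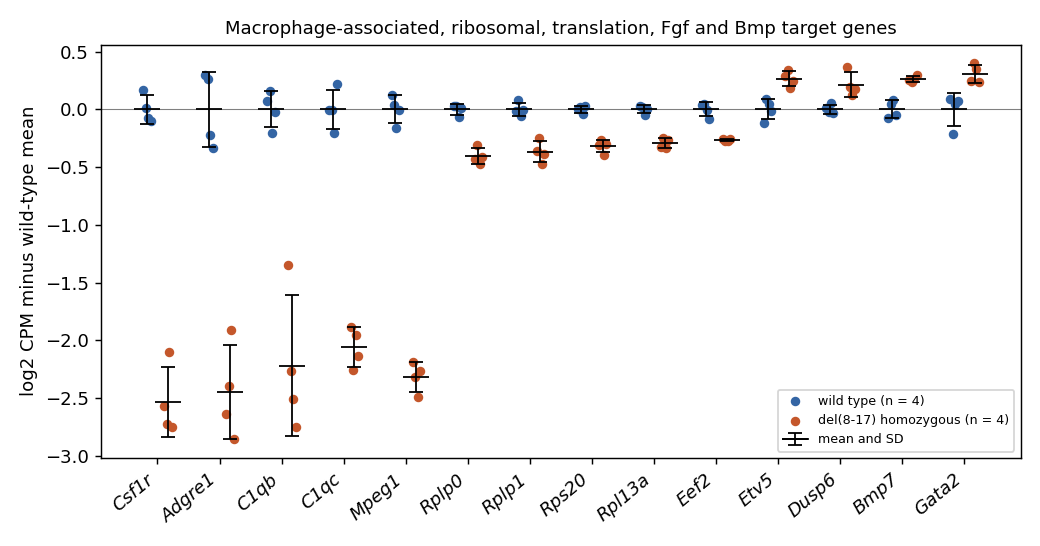
Log2 CPM minus the wild-type mean for 14 genes in each library, with the mean and SD of each group (n = 4). The mutants lie below all wild types for the first 10 genes and above them for the last 4.

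Among genes past the edgeR threshold with mean log2 CPM above 0 and no overlap between groups, the largest rises were those of the pseudogene Eif3s6-ps2 (3.73, SE 0.376, edgeR adjusted p = 2.84e-05; 0.195 ± 0.144 CPM in wild type and 2.72 ± 0.522 in mutants, SD, n = 4), Gm53 (1.48), Agr3 (1.36), Kcnh8 (0.88), Tmem132d (0.69), Sh3rf2 (0.67), Gm9866 (0.58), Ntm (0.56), the adhesion gene Nectin4 (0.52) and the transcription factor gene Casz1 (0.49). Of these 10, only Eif3s6-ps2 kept its call in each of the 8 fits that left out 1 library. Y-linked genes were detected in wild-type replicate 3, with 3194 counts over 4 genes, and in mutant replicate 3, with 1160. The other 6 libraries held at most 11. Xist, the RNA of the inactive X chromosome, had 83 and 23 counts in those 2 libraries and at least 14430 in the others, so each group held 1 library of this kind.

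The deposited lists held 16985 H3K27ac and 31619 H3K4me1 peaks, with median widths of 1034 and 1661 bp. Of the H3K27ac peaks, 66.5% overlapped an H3K4me1 peak by at least 1 bp, against 7.05% after the H3K4me1 peaks were shifted by 500 kb. Mean H3K27ac coverage over its peaks was 8.43 times the genome mean, and input over the same peaks was 1.10. For H3K4me1 the values were 4.76 and 1.10. There is no replicate check on these values. The peaks were called on these same ChIP libraries, so high coverage over them follows in part from how they were chosen.

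The region of Myc was examined in a window on chromosome 15 from 61 to 64 Mb, which was set to hold Myc and the gene desert beside it. The ends of the deletion are not given by the labels, so no value is assigned to the deleted part. The window held 8 H3K27ac and 27 H3K4me1 peaks, where the median over 2589 windows of 3 Mb was 14 and 29. Fewer H3K27ac peaks were found in 31.02% of those windows and fewer H3K4me1 peaks in 47.1%. Of the 8, 2 overlapped an H3K4me1 peak, a count that depends on the peak cutoff. Without overlap, the peaks starting at 61021293, 61819319 and 63948453 had H3K4me1 coverage of 4.32, 3.93 and 3.89 times the genome mean. Those starting at 61815666, 61816893 and 63914039 had 1.49, 1.90 and 2.26. The overlapping peak starting at 63828728 had 1.64, and the lowest value of an H3K4me1 peak in the window was 3.64. The 2 highest H3K27ac scores in the window were 345.47 at 61815666 to 61816887 and 360.97 at 61816893 to 61819069, with coverage of 9.24 and 7.80 times the genome mean against 1.04 and 1.23 in input. Between 61819879 and 63828727, a stretch chosen after the peaks were seen, 21 H3K4me1 peaks and 1 H3K27ac peak lay wholly inside, and 1 more H3K4me1 peak, at 63827345 to 63829149, reached across its end. That H3K27ac peak, at 62884360 to 62884867, had a score of 59.01, where the lowest in the list is 50.02, with 5.43 times the genome mean in H3K27ac and 0.870 in input. It lay wholly within the H3K4me1 peak at 62883564 to 62885030.

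**Figure D4:**
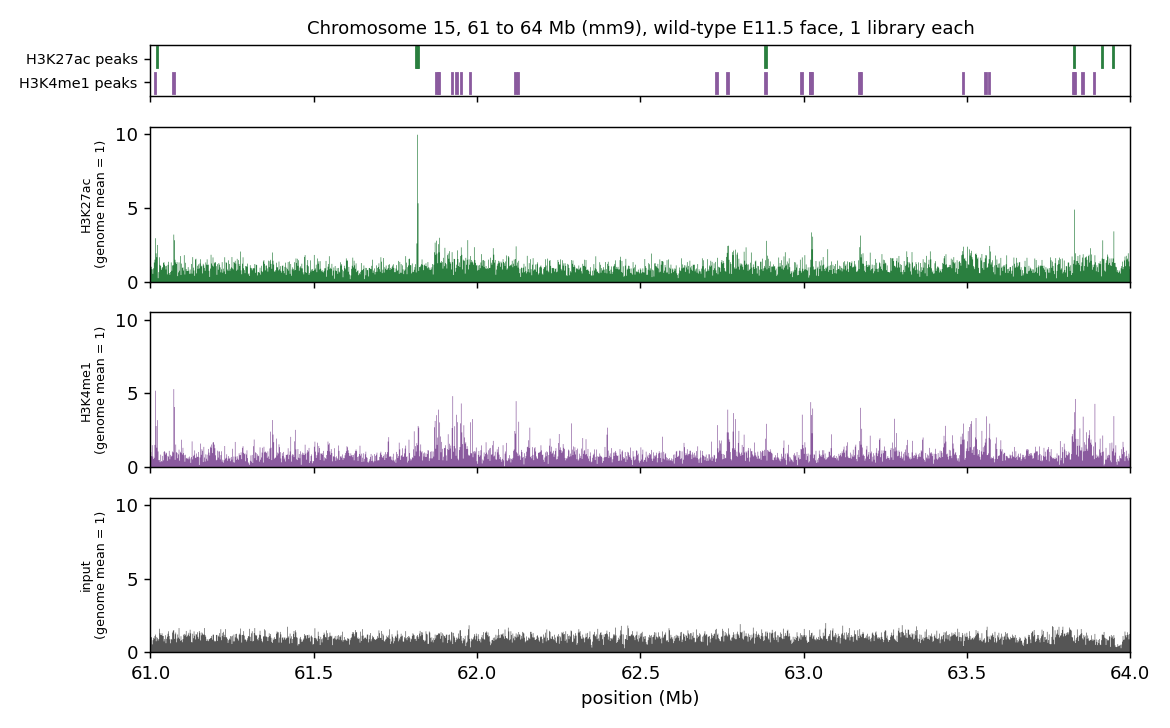
Peaks (top, widened by 1.5 kb on each side to be visible) and coverage in bins of 2 kb relative to the genome mean of 1, for 1 library each, on chromosome 15 from 61 to 64 Mb in mm9. The 8 H3K27ac peaks include 1 between 61819879 and 63828727.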

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

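The tests of blood content, macrophage number, short mRNAs and reads of Eif3e, and the thinning of libraries, were chosen after the result they concern had been seen. The count of lists over splits with an estimated correlation was added after that with the preset correlation was known. The splits balanced by litter were also added after the other splits had been seen. The other tests in this part were set before their own outcome was known. Those on macrophage transcripts, ribosomal protein mRNAs and Eif3s6-ps2 concern patterns picked from these same data.

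The 8 libraries can be parted into 4 and 4 in 35 ways. The genotypes gave 142 genes and no other split gave more than 3, so only 1 of the 35 splits gave as many. This share is under 0.05 only if the litters are set aside. Of these splits, 20 put as many libraries of each litter into either group, and the highest other of them also gave 3 genes; 20 splits are too few for a share under 0.05. For the number of lists called with the preset correlation chance cannot be excluded. As many as the 13 of the genotypes were called in 6 of the 35 splits, and the highest other split called 15. The other splits among those 6 moved 1 or 3 libraries out of the wild-type group, so they kept part of the genotype difference. Of the splits that moved 2, the highest called 11 lists. With an estimated correlation the genotypes called 6 lists and the highest other split 0, so 1 of 35 splits gave as many, with the same limit.

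The fall of macrophage transcripts had a median of -1.91, and the furthest median of any other split lay 1.17 from 0. That split moved 1 library of each group and so kept part of the genotype difference. The list was followed up because of its fall, so 1 of 35 splits with as large a value decides nothing about chance. Less whole blood in the mutant dissections is argued against by the erythroid list, whose lowest member had -0.44, above -0.956, which is 0.5 times the macrophage median, but genes of other blood cells fell (Mpo -2.73, Ighm -3.39, and Pf4 -0.78 and Tubb1 -0.77, both chosen after their values were seen), so a loss of white cells or platelets is not excluded. The erythroid list was however called lower without wild-type replicate 1 (adjusted p = 2.87e-06, median -0.22) and in litter 214676 alone (adjusted p = 5.67e-06, median -0.23), against 0.157 to 0.942 in its other alternatives. Depth is argued against by thinning, which left the macrophage median at -1.89 with 8 of 12 members called. Fewer macrophages in the mutant faces and lower expression per cell both stay open and cannot be told apart: that 14 of 14 members lay below 0 restates the fall and decides nothing.

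The fall of cytosolic ribosomal protein mRNAs had a median of -0.23, against at most 0.153 from 0 in the other splits. The split with 0.153 moved 1 library of each group, and this list too was followed up because of its fall. That 1 of 35 splits gave as large a value therefore decides nothing about chance. An equal loss of all short mRNAs is argued against by mitochondrial ribosomal proteins, with a median of -0.047 (95% bootstrap interval -0.070 to -0.029). However, 58 of those 73 genes also lay below 0, and transcript length was not measured. A partial effect of length is therefore left open. A bias of abundant mRNAs is argued against by 10000 random lists matched on mean expression, the lowest of which had a median of -0.037. A move of reads to pseudogenes was looked for in the 9 tested ribosomal protein pseudogenes whose symbol ends in -ps and a number or none. Their median was -0.21 (interval -0.35 to -0.087), which argues against a move to these 9. Pseudogenes under other names were not examined, and how shared reads were counted is not given. A move of reads elsewhere is therefore left open. A lower level of these mRNAs in the mutant faces is left as a hypothesis, and whether it follows from Myc in the same cells was not tested.

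The rise of Eif3s6-ps2 may come from reads of Eif3e, for which Eif3s6 is a synonym. The gain was 2.53 CPM and Eif3e lost 30.96 CPM (SE 4.601), so the gain neither equals nor exceeds that loss and the test does not decide. For strain variants linked to the deletion, calls on chromosome 15 were counted, and 11 of 512 tested genes there other than Myc were called (odds ratio 2.14, Fisher's exact p = 0.0239, which met the criterion set beforehand, but 0.239 when adjusted over 20 chromosomes, a step added after the value was seen), while chromosome 7 had 20 of 986 (odds ratio 2.09, p = 0.00505, adjusted 0.101). The 11 include Nckap1l, Rac2, Cyth4 and Fyb, genes of blood cells, and Rpl8, Rpl3, Pabpc1 and Eif4b, genes of translation, and the count says nothing about Eif3s6-ps2, which lies on chromosome 18, while Eif3e lies on chromosome 15. Reads of Eif3e and a change at the pseudogene itself cannot be told apart, because single reads were not examined here.

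A library stood apart from the other 3 of its group in 12 of 224 sets of values, where chance gives about 11.2, or 1 in 20. The gap as a share of the group's range was 0.856 for Sqle and 0.918 for Cdkn1c in wild-type replicate 1, 0.850 for Gata2 and 0.923 for Ldha in wild-type replicate 2, and 0.866 for Cldn6 in wild-type replicate 3. It was 0.944 for Fam49b, 0.837 for Nectin4, 0.860 for Aldoa and 0.876 for Npm1 in mutant replicate 3, and 0.887 for Mrpl34 in mutant replicate 4. For Xist it was 0.966 in wild-type replicate 3 and 0.989 in mutant replicate 3, the libraries with Y-linked transcripts. The genotype effect on Dkk1 differed between the litters by 0.93 on the log2 scale (edgeR interaction, adjusted p = 0.0163), where litter 214262 has 1 library per genotype.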

How the results depend on the processing

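Removal of the 2 libraries with Y-linked transcripts, thinning, and removal of Myc from the lists were chosen after seeing the data. Myc kept its direction and call in each alternative, between -2.69 and -2.50 with each library left out. The count of 142 genes (36 higher, 106 lower) was 255 (76 and 179) without a filter, which tests more genes, and 72 (9 and 63) with thinned libraries, which hold fewer counts. It was 82 at a threshold of 0.01, with 9 higher, and 60 were higher at 0.1. In litter 214676 alone 70 were higher, and without the Y-linked libraries 16; the cause was not tested. With each library left out, 86 (without mutant replicate 4) to 161 genes were called, 14 to 52 higher and 72 to 109 lower. The litter as a block gave 124 genes, 121 of them shared with the 142, and DESeq2 gave 143, of which 126 were shared. The 13 called lists became 6 with an estimated correlation, and 12 to 16 with a library left out. Of 38 named genes with a call, 22 kept it in each of the 8 fits that left out 1 library. Hypoxia and glycolysis lost its call without wild-type replicate 3 (adjusted p = 0.0842), mutant replicate 1 (0.0518) or the Y-linked libraries (0.140), with thinning (0.0646) and with fry (0.0818), and neurons and olfactory placode without mutant replicate 4 (0.157). With fry, neurons (0.192) and surface ectoderm (0.0786) also lost the call, while the Myc family (0.000245) and Myc neighbours (0.00243), which hold Myc, gained one.

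Several genes near 0 that did not pass changed sign; the cause was not tested. Ndrg1 had -0.056 without the Y-linked libraries and -0.032 to 0.075 with a library left out. Tmem65 had 0.0050 without a filter, 0.046 in litter 214676, 0.0070 with DESeq2, 0.023 with voom, 0.0078 with legacy=TRUE, 0.014 without the Y-linked libraries and -0.042 to 0.030 with a library left out. Thinning gave Fam49b 0.00016, Fam91a1 -0.014 and Nsmce2 -0.063. Fam91a1 had -0.021 in litter 214676 and -0.017 to 0.033 with a library left out, Nsmce2 -0.00086 to 0.040, and Xist -0.17 to 0.65. Adjusted p of lists that changed direction was 0.811 for neural epithelium without a filter, 0.314 for it, 0.450 for cell cycle and 0.852 for erythroid without the Y-linked libraries, 0.894 for p53 targets in litter 214676, and 0.534 for the Myc family without Myc. Over all fits with a library left out, reversed or not, it was 0.245 to 0.906 for cell cycle and 0.169 to 0.994 for neural epithelium. In those fits it was 2.87e-06 to 0.942 for erythroid, 0.633 to 0.932 for immediate early genes and 0.169 to 0.799 for Hedgehog targets. Among them the erythroid list changed direction only without wild-type replicate 4 (camera adjusted p = 0.760), and it stayed lower at 2.87e-06. Of 1953 values of named genes under alternatives, 142 lost the call, 36 gained it and 22 changed sign.

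The overlap of 66.5% was 46.0% at 50% of peak length and 45.1% among the higher-scoring peaks of each list. Coverage over input was 7.66 for H3K27ac (median 6.64, higher-scoring peaks 10.01) and 4.34 for H3K4me1 (4.23 and 4.79). The window held 3 H3K27ac and 9 H3K4me1 of the higher-scoring peaks, and 14 and 44 peaks when set from 60 to 65 Mb. The 2 overlapping H3K27ac peaks became 1 among the higher-scoring peaks, 1 at 50% of length and 8 in the wider window. Scaling to the fly spike-in and mouse RNA relative to it were not run, so a change of all mRNAs together would not be seen.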

Other observations

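Genes named in this part were chosen after their values were seen. Single genes that fell with edgeR were Pabpc1, the poly(A)-binding protein gene (-0.29), Rack1 (-0.25), Eif4b (-0.20), Tpt1 (-0.19), the snoRNA host Gas5 (-0.25), the glycolytic genes Tpi1 (-0.26) and Gpi1 (-0.24) and the lactate transporter gene Slc16a3 (-0.43). They were not tested as a group, and in the fixed list of translation factors and tRNA synthetases 3 of 38 members fell and 9 lay above 0. The platelet genes Pf4, which is in the list of macrophages and blood cells, and Tubb1 fell by 0.78 and 0.77. Lyve1, a gene of lymphatic endothelium and some macrophages, rose from 0.201 ± 0.0608 to 2.21 ± 0.906 CPM (SD, n = 4; edgeR adjusted p = 0.00124). The matrix gene Vcan (0.28), the signalling antagonist gene Nbl1 (0.26) and the channel gene Ano1 (0.47) rose.

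On chromosome X there were 411 of the 16985 H3K27ac peaks and 104 of the 31619 H3K4me1 peaks, with mean coverage of 0.572 and 0.570 times the genome mean and 0.759 in input.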
